A study of Rattus norvegicus with 12 samples.

How the data were processed

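Total RNA of rat liver was hybridized to Affymetrix rat expression arrays, 12 in all, with biotin-labelled RNA prepared from 3 µg of total RNA per the labels' protocols. The values used are log2 expression values in the table the authors deposited, made with RMA in R 2.6.1 per the submitters' processing notes. RMA subtracts background, normalizes arrays by quantiles and summarizes probes into probe sets. Whether the 12 arrays were normalized together is not stated, and their medians lay between 7.39 and 7.51. The deposited values were not normalized again for the main results.

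Groups were taken from the sample titles: 4 nontumor and 4 tumor arrays of LEC liver at 67 weeks, and 1 array each of LEA at 67 weeks and LEC at 4, 26 and 39 weeks. Each tumor or nontumor array pooled RNA of 2 of 8 paired specimens, in 4 sets. How many rats were in the other pools, whether a rat is in more than 1 pool and whether a title number marks a set are not stated. The design, gene lists, named-gene rule and most alternatives were set before the data were examined; the alternatives that split the nontumor arrays were chosen after seeing the data.

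Of 31099 probe sets, 57 controls were left out of the tests and 31042 were tested. The annotation table gave 20826 of these a single gene, 436 several and 9780 no gene listed here; symbols were updated through Entrez identifiers, of which 20758 matched, and no gene was named from a probe set with several. A gene was represented by the probe set with the highest mean over the 12 arrays, giving 14217 genes.

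One model of group means over all 12 arrays was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. It had 6 residual degrees of freedom and 2.84 of the prior. Lone arrays add nothing to the spread and were assumed to vary like the replicated groups. Two-sided p-values were adjusted by Benjamini-Hochberg over the 31042 probe sets, with a threshold of 0.05. Each of the 4 nontumor and 4 tumor arrays was also tested alone against the other 3 of its group to count calls of a lone array. Age pools were compared with each other only by 2-fold differences and by list medians against 10000 random lists matched on mean expression.

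Gene lists numbered 35, with 818 entries of which 721 matched a measured gene, and covered liver metabolism, stress, immunity, growth and cell types (hepatocyte, bile duct, matrix, endothelium, macrophage, T, B and NK cell, neutrophil, red blood cell, and pancreas, fat and muscle). They were tested with limma's camera at a preset correlation of 0.01, adjusted over the 35 lists, beside camera with an estimated correlation and fry. Members were also counted past adjusted p over all probe sets and adjusted over the list alone. The genes named in the text were, for tumor against nontumor and for LEC against LEA, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap. Up to 4 members of each called list were added, and Atp7b, Mt1, Mt2A, Cp, Hamp, Gstp1, Afp, Ggt1, Gpc3 and Alb always. For the other comparisons the 5 largest rises and falls were taken, with the same list members and fixed genes. Symbols that stand for uncharacterized loci were passed over. Not every gene the rule gives is printed, and Xist and Eif2s3y values on single arrays were chosen after their values were seen. The comparison of named genes with probe sets for absent bacterial RNA was also chosen then.

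The test was tested on simulated data with 200 of 31042 probe sets changed. For tumor against nontumor it called 155, of which 9 were false, and recovered 15, 34, 48 and 49 of 50 probe sets changed by 0.5, 1, 2 and 4 log2 units. For LEC nontumor against LEA it called 134, of which 8 were false, and recovered 4, 27, 45 and 50. In the simulated list test for tumor against nontumor, on 14217 genes, 1 list of 35 was shifted by 1 log2 unit, and it was called and 0 others. The simulated genes varied independently of each other, so this does not check the calls of lists whose genes vary together.

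Alternatives were quantile normalization again, subtraction of array medians, removal of dim probe sets (mean at or below the median of means), a 2-fold threshold, a trended robust prior, array weights, means over the probe sets of a gene, spread from a single group, the title number as a block, and leaving out each replicate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No genome coordinates were used here.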

Results

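Liver RNA of Long Evans Cinnamon (LEC) rats was profiled on 12 Affymetrix rat expression arrays, together with RNA of Long Evans Agouti (LEA) rats as controls. LEC rats carry a defective copper transporter gene, Atp7b, accumulate copper in the liver and develop hepatitis and liver tumors with age. There were 4 arrays of tumor and 4 of nontumor liver at 67 weeks, each made from RNA of 2 tumor and nontumor pairs drawn at random from 8. The other 4 arrays were single RNA pools of LEC liver at 4, 26 and 39 weeks and of LEA liver at 67 weeks. Whether a rat entered more than 1 pool is not stated, so p-values of single probe sets measure only the spread between these samples. Camera compares the genes of a list with all other genes, at a preset correlation of 0.01 between genes. Its p-values set genes against genes and do not measure that spread. The number of arrays limits the precision of every value. Differences are in log2 units ± standard error from limma, and levels are log2 means ± SD. Gene lists are called by limma's camera unless fry is named.

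The arrays separated first by tumor, with 76.6% of the variance on the first principal component and 6.41% on the second. Correlations across probe sets, which are not independent replicates, lay between 0.968 and 0.994 within the tumor arrays and between 0.975 and 0.993 within the nontumor arrays. Across the groups they lay between 0.845 and 0.933. Every label gives the rats as male. Xist, the RNA that silences an X chromosome in female cells, lay by its brightest probe set between 11.36 and 13.12 on 10 arrays. It lay at 5.27 on the array labelled 26 weeks and 5.67 on the array labelled 39 weeks. Eif2s3y, a gene of the Y chromosome, lay at 8.90 and 8.18 on those arrays and between 3.65 and 3.81 on the other 10. The lowest Xist value of the 10 arrays exceeded the higher of the 26 and 39 week values by 5.68 for the brightest probe set and by 5.34, 2.61 and 2.36 for the other probe sets. The median of the male-biased liver genes exceeded that of the female-biased genes by 3.75 and 4.32 on the arrays labelled 26 and 39 weeks and by 2.53 on the array labelled 4 weeks. On the LEA array this difference was -4.00. The highest probe set for absent bacterial RNA lay at 5.95 on the nontumor, 5.59 on the tumor and 6.11 on the LEA arrays, and a gene whose lower level lies within that range has no exact difference.

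**Figure D1:**
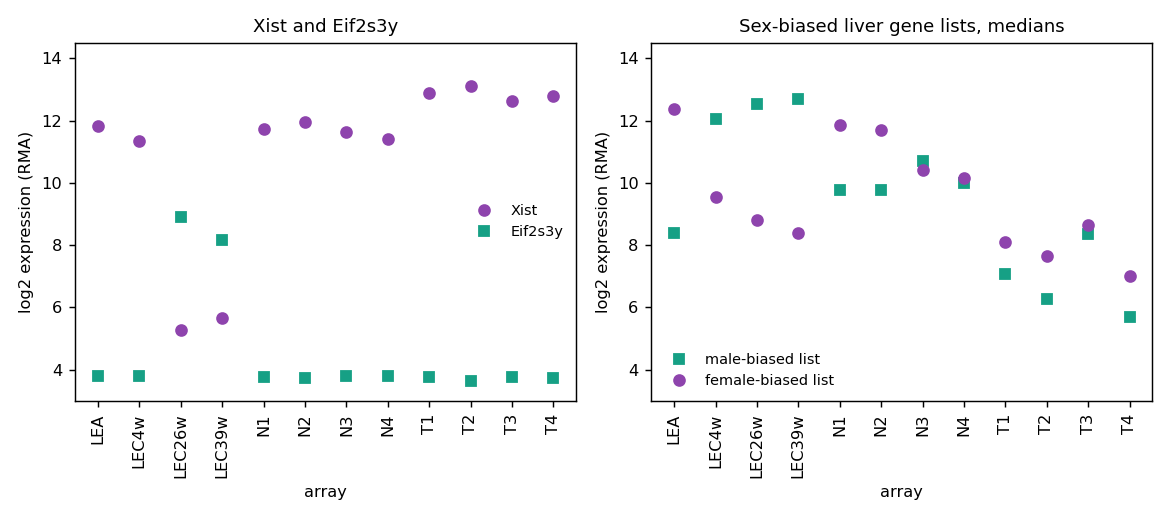
Log2 expression of Xist, by its brightest probe set, and Eif2s3y (left) and the medians of the male-biased and female-biased liver gene lists (right) on each of the 12 arrays, with each point a single array (N nontumor, T tumor). Xist lies at 5.27 and 5.67 on the arrays labelled 26 and 39 weeks and at or above 11.36 on the other 10.

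Tumor and nontumor liver of the same age were compared to find the genes that differ in the tumors. Lumican (Lum), a proteoglycan that binds collagen, rose (5.45 ± 0.47) from 5.26 ± 0.58 in nontumor to 10.71 ± 0.97 in tumor arrays (n = 4 each). The chemokine Cxcl6, which attracts neutrophils, rose 43.7-fold (5.45 ± 0.37), and the sugar-binding galectin Lgals4 rose (5.40 ± 0.43). The GABA receptor subunit Gabrp (5.33 ± 0.17), the cell-surface glycoprotein mesothelin, Msln (5.20 ± 0.24), the transcription factor Klf5 (5.10 ± 0.30) and the microtubule protein Map2 (5.05 ± 0.27) also rose. So did the ankyrin repeat protein Ankrd1 (5.01 ± 0.15), the synuclein Sncg (4.94 ± 0.28) and skeletal muscle actin, Acta1 (4.63 ± 0.20). Their adjusted p-values lay between 5.6e-07 for Gabrp and 2.4e-05 for Lum. The nontumor levels of Lum, Acta1 and Map2 lay within the range of probe sets for absent RNA, as did Lgals4 and Klf5 on nontumor arrays 1 and 4 and Ankrd1 on arrays 1 and 3. The aldo-keto reductase Akr1b7 fell (-4.91 ± 0.74, adjusted p = 5.1e-04). Cd5l, secreted by macrophages (-4.82 ± 0.57), the protease inhibitor Mug1 (-4.63 ± 0.96), the bile acid enzyme Cyp8b1 (-4.62 ± 0.56) and the corticosteroid carrier Serpina6 (-4.60 ± 0.78) fell. Falls were also found in the steroid hydroxylase Cyp17a1 (-4.31 ± 0.69), the carbonic anhydrase Car3 (-4.29 ± 0.61), the glucuronosyltransferase Ugt2b1 (-4.25 ± 0.54), Cyp2d3 (-4.20 ± 0.52) and the choline-pathway enzyme Dmgdh (-4.17 ± 0.62). Without tumor array 4 the differences of Akr1b7, Cd5l, Mug1, Serpina6 and Cyp17a1 were -4.22, -4.19, -3.71, -3.87 and -3.65, and without tumor array 3 those of Mug1, Serpina6 and Car3 were -5.50, -5.21 and -4.91. On tumor array 4, Akr1b7, Cd5l, Mug1, Serpina6, Cyp17a1 and Dmgdh lay within the range of probe sets for absent RNA, as did Bhmt and Hjv, and Gys2 and Elovl2 on tumor arrays 2 and 4. Of these genes, tumor array 3 stood highest for Car3 (8.25, next 6.05), tumor array 3 stood lowest for Msln (13.18, next 13.78) and nontumor array 2 stood highest for Msln (9.17, next 8.27).

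**Figure D2:**
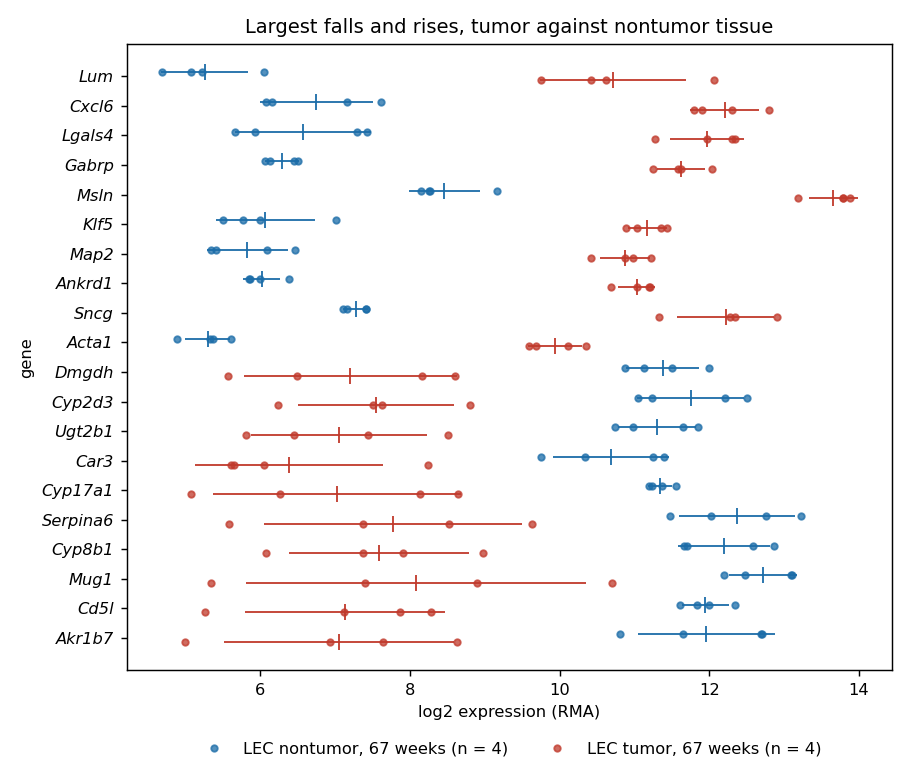
Log2 expression of the 10 genes with the largest rise and the 10 with the largest fall on each tumor and nontumor array; points are arrays, vertical ticks are group means and horizontal bars are 1 SD (n = 4). The genes were chosen among those whose groups do not overlap, as 63.8% of all genes do not. Tumor arrays spread more than nontumor arrays for Mug1 (8.09 ± 2.27 against 12.71 ± 0.46).

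Beside the counts of list members that follow, 5511 of all 14217 genes rose and 4147 fell. All 31 measured genes of urea cycle and amino acid breakdown fell, including the betaine enzyme Bhmt (-4.13 ± 0.78) and Upb1 of pyrimidine breakdown (-3.96 ± 0.85). The differences of Bhmt and Upb1 were -3.34 and -3.08 without tumor array 4 and -4.72 and -4.59 without tumor array 3. The urea cycle list had adjusted p = 1.3e-09, and adjusted p = 0.393 with an estimated correlation, and 31 fell when adjusted over the list alone. Of the cytochrome P450 genes of drug metabolism 18 of 20 fell, such as Cyp1a2 (-4.12 ± 0.52). Drug metabolism had adjusted p = 1.2e-05, and adjusted p = 0.393 with an estimated correlation, and 19 fell when adjusted over the list alone. On the median of this list, nontumor array 4 stood lowest (11.07, next 11.85). In bile acid synthesis and transport 2 rose and 19 fell of 23, with the export pump Abcc2 among the falls (-4.11 ± 0.43) and Cyp7b1 (0.68 ± 0.18) and the exporter Abcc4 (0.84 ± 0.23) as the rises. The bile acid list had adjusted p = 2.1e-05, and adjusted p = 0.393 with an estimated correlation, and 3 rose and 19 fell when adjusted over the list alone. For Cyp7b1, tumor array 4 stood lowest (6.54, next 7.11) and nontumor array 3 stood highest (6.76, next 6.21). Gluconeogenesis and glycogen genes fell in 13 of 14 cases, among them glycogen synthase, Gys2 (-3.27 ± 0.41), and the gluconeogenesis enzyme Fbp1 (-3.07 ± 0.31). The gluconeogenesis list had adjusted p = 1.4e-05, and adjusted p = 0.393 with an estimated correlation, and 13 fell when adjusted over the list alone.

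Fatty acid oxidation genes fell in 20 of 24, with the fatty acid carrier Fabp1 at -3.77 ± 0.94 and Cyp4a1 at -3.88 ± 0.79. Fatty acid oxidation had adjusted p = 5.0e-07, and adjusted p = 0.393 with an estimated correlation, and 20 fell when adjusted over the list alone. Fatty acid and triglyceride synthesis genes fell in 16 of 20, with the lipogenic regulator Thrsp at -3.62 ± 0.97 and the elongase Elovl2 at -3.47 ± 0.58. Fatty acid synthesis had adjusted p = 2.1e-05, and adjusted p = 0.393 with an estimated correlation, and 16 fell when adjusted over the list alone. Leaving out tumor array 4 gave -2.80, -3.04 and -2.70 for Fabp1, Cyp4a1 and Thrsp, and leaving out tumor array 3 gave -4.62, -4.35 and -4.08 for Fabp1, Thrsp and Elovl2. For these genes, tumor array 3 stood highest for Elovl2 (8.09, next 5.93) and nontumor array 1 stood highest for Thrsp (13.82, next 12.66). Cholesterol synthesis genes fell in 12 of 20, as in Tm7sf2, a sterol reductase (-2.75 ± 0.48). Cholesterol synthesis had adjusted p = 0.00104, and adjusted p = 0.582 with an estimated correlation, and 12 fell when adjusted over the list alone. This call was lost with nontumor arrays 3 and 4 alone (adjusted p = 0.0726). On the list median, tumor array 3 stood highest (9.88, next 9.32). The respiratory chain fell in 18 of 30 genes by smaller amounts, for example the cytochrome oxidase subunit Cox5a (-0.65 ± 0.09). The respiratory chain had adjusted p = 5.5e-05, and adjusted p = 0.396 with an estimated correlation, and 18 fell when adjusted over the list alone.

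Secreted hepatocyte proteins fell in 20 of 28 genes, including coagulation factor F10 (-3.65 ± 0.79) and protein C, Proc (-3.33 ± 0.67). F10 and Proc stood at -2.87 and -2.67 without tumor array 4, and F10 at -4.37 without tumor array 3. The secreted protein list had adjusted p = 4.1e-05, and adjusted p = 0.582 with an estimated correlation, and 24 fell when adjusted over the list alone. Relative to the nontumor arrays, its median change ranged from -5.31 in tumor array 4 to -0.63 in tumor array 3. Over all tumor arrays it was -2.54, and -1.48 without tumor array 4 or -3.19 without tumor array 3. Matrix and stellate cell genes rose in 35 of 38, including the matricellular growth factor Ccn2 (4.33 ± 0.31). Matrix and stellate cells had adjusted p = 8.8e-11, and adjusted p = 0.393 with an estimated correlation, and 35 rose when adjusted over the list alone. All 15 bile duct and progenitor cell genes rose, among them the keratins Krt7 (4.61 ± 0.19) and Krt19 (4.41 ± 0.41). The bile duct list had adjusted p = 3.6e-06, and adjusted p = 0.393 with an estimated correlation, and 15 rose when adjusted over the list alone. Endothelial genes had a median of 0.48, a mean of -0.04 and no call by camera (10 rose and 7 fell of 19, adjusted p = 0.717). Macrophage genes (13 rose and 3 fell of 21, adjusted p = 0.128) and neutrophil genes (9 rose and 3 fell of 14, adjusted p = 0.224) were not called by camera, and tumor array 3 stood highest for the neutrophil and mast cell list median (7.99, next 7.47). Camera did not call T, B and NK cell genes either (11 rose and 8 fell of 27, adjusted p = 0.642), with a median of -0.02, a mean of 0.35 and a median of 0.07 when the arrays were quantile normalized again. Fry tests whether the genes of a list move on balance one way and compares them with no other genes. It called all 4 lists higher, endothelial genes with adjusted p = 0.0491, macrophage genes with adjusted p = 0.0175, neutrophil genes with adjusted p = 1.6e-04 and T, B and NK cell genes with adjusted p = 0.00129. Fry was not run after quantile normalization again. That step moved the medians from 0.48 to 0.20 for endothelial, 0.54 to 0.35 for macrophage and 0.65 to 0.45 for neutrophil genes.

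**Figure D3:**
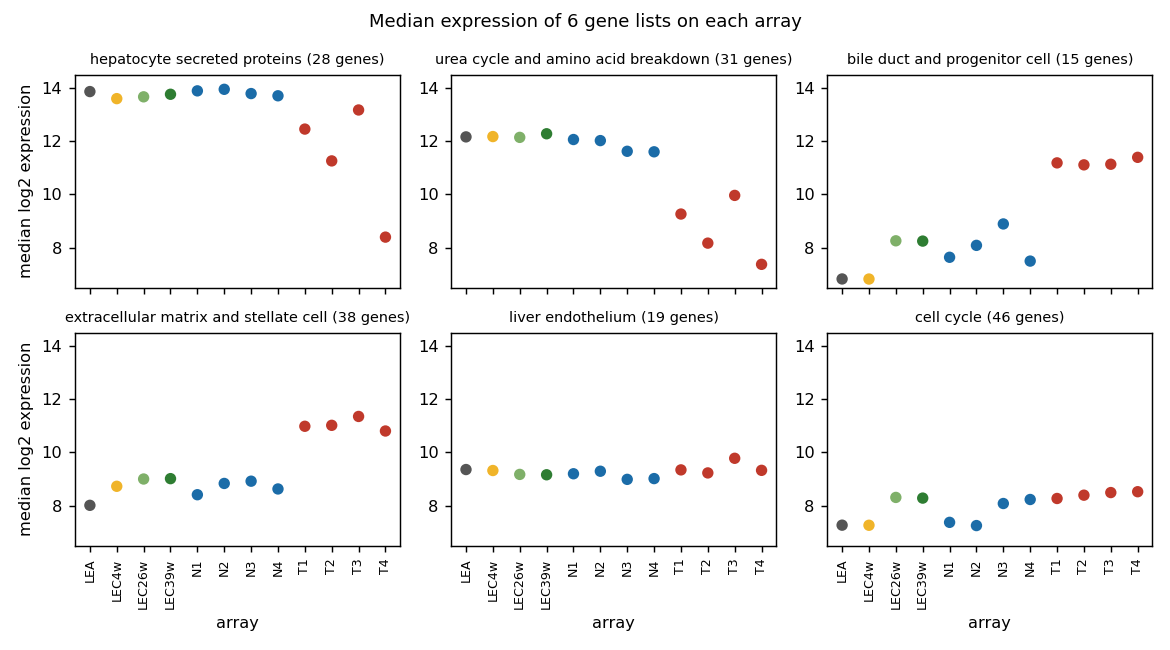
Median log2 expression of 6 gene lists on each of the 12 arrays (blue nontumor N, red tumor T, grey LEA, yellow and green LEC pools); points are single arrays without error bars. The bile duct list lies between 11.11 and 11.39 on the tumor arrays and at or below 8.89 on all others, and the endothelial list between 8.99 and 9.78 on all 12.

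Red blood cell genes fell in 4 of 7, such as the hemoglobin chaperone Ahsp (-1.12 ± 0.21). The red blood cell list had adjusted p = 0.0281, and adjusted p = 0.393 with an estimated correlation, and 4 fell when adjusted over the list alone. The red blood cell call was lost without dim probe sets and with nontumor arrays 3 and 4 alone (adjusted p from 0.112 to 0.25). Of pancreas, fat and muscle genes 2 rose and 11 fell of 18, with the elastase Cela1 (2.61 ± 0.24) and the fat hormone Adipoq (0.80 ± 0.16) rising and Cpa1 (-1.60 ± 0.23) and the lipid droplet gene Cidec (-2.54 ± 0.30) among the falls. Pancreas, fat and muscle had adjusted p = 0.00495, and adjusted p = 0.393 with an estimated correlation, and 2 rose and 11 fell when adjusted over the list alone. It was lost with quantile normalization again and without dim probe sets (adjusted p from 0.0671 to 0.827). The median was -0.32, and 0.26 without dim probe sets. The tumor level of Cpa1 lay within the range of probe sets for absent RNA. In the male-biased list 1 rose and 11 fell of 15, with the transporter Slco1a1 at -4.00 ± 0.50. Male-biased liver genes had adjusted p = 0.00211, and adjusted p = 0.396 with an estimated correlation, and 1 rose and 12 fell when adjusted over the list alone. In the female-biased list 1 rose and 12 fell of 14, with Fmo2 as the rise (1.04 ± 0.14). Female-biased liver genes had adjusted p = 7.3e-04, and adjusted p = 0.393 with an estimated correlation, and 1 rose and 12 fell when adjusted over the list alone.

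Cell cycle genes rose in 23 of 46 and fell in 2, with the mitotic kinesin Kif23 at 2.21 ± 0.16 and cyclin Ccna2, whose nontumor level lay within the range of probe sets for absent RNA, at 2.10 ± 0.22. The cell cycle list had adjusted p = 0.00495, and adjusted p = 0.606 with an estimated correlation, and 23 rose and 2 fell when adjusted over the list alone. The list median was 7.37, 7.25, 8.08 and 8.23 on nontumor arrays 1 to 4 and between 8.27 and 8.53 on the tumor arrays. The cell cycle call was lost without dim probe sets and with nontumor arrays 3 and 4 alone (adjusted p from 0.0744 to 0.313). The settings with some nontumor arrays alone were chosen after seeing the data. All 8 class II antigen presentation genes rose, with RT1-Da at 2.80 ± 0.15 and RT1-Bb at 2.72 ± 0.15. The class II list had adjusted p = 5.6e-04, and adjusted p = 0.393 with an estimated correlation, and 8 rose when adjusted over the list alone. A further probe set of Kif23 and of RT1-Bb was not called in the same direction. Of inflammatory cytokines and chemokines 15 rose and 4 fell of 25, with Ccl2 (3.93 ± 0.30) and Ccl20 (3.88 ± 0.16) rising and Il1a (-2.21 ± 0.16) and Ccl6 (-1.57 ± 0.25) falling. The cytokine list had adjusted p = 0.0183, and adjusted p = 0.393 with an estimated correlation, and 15 rose and 4 fell when adjusted over the list alone. The cytokine call was lost without tumor array 3, without dim probe sets and with nontumor arrays 3 and 4 alone (adjusted p from 0.0524 to 0.0846). For Ccl6, tumor array 3 stood highest (11.20, next 10.35). Of acute phase genes 3 rose and 10 fell of 20, with the protease inhibitor Serpina3m at -3.49 ± 0.57, the fibrinogen chain Fgb at -2.92 ± 1.01 and Lcn2 at 1.55 ± 0.28. The acute phase list had adjusted p = 0.0341, and adjusted p = 0.606 with an estimated correlation, and 3 rose and 10 fell when adjusted over the list alone. The acute phase call was lost without nontumor array 2 or 3, with means per gene, with quantile normalization again, with nontumor arrays 1 and 2 alone and with nontumor arrays 3 and 4 alone (adjusted p from 0.0578 to 0.112). Fry did not call it either (adjusted p = 0.162). The acute phase median moved from -1.62 to -0.73 without tumor array 4, and Fgb to -1.82, or to -3.67 without tumor array 3. Fgb lost its call without nontumor array 1, 2, 3 or 4 or tumor array 2 (adjusted p from 0.0544 to 0.0698).

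Targets of the oxidative stress regulator NRF2 were called lower as a list, while 5 rose and 17 fell of 24. The NRF2 list had adjusted p = 0.0144, and adjusted p = 0.506 with an estimated correlation, and 6 rose and 17 fell when adjusted over the list alone. The NRF2 call was lost with nontumor arrays 1 and 2 alone (adjusted p = 0.0952). The glutathione peroxidase Gpx2 rose (4.12 ± 0.48) and the glutathione transferase Gsta3 fell (-2.95 ± 0.69). Of antioxidant enzymes 3 rose and 12 fell of 18, with Gpx3 (2.63 ± 0.20) and the secreted superoxide dismutase Sod3 (1.89 ± 0.29) rising and catalase, Cat (-1.62 ± 0.43), and the methionine sulfoxide reductase Msra (-1.95 ± 0.14) falling. Antioxidant enzymes had adjusted p = 0.00764, and adjusted p = 0.393 with an estimated correlation, and 3 rose and 13 fell when adjusted over the list alone. Of ER stress genes 1 rose and 9 fell of 23, with asparagine synthetase, Asns, as the rise (1.90 ± 0.23) and Dnajc3 (-1.61 ± 0.17) and Trib3 (-1.47 ± 0.25) among the falls. The ER stress list had adjusted p = 0.0471, and adjusted p = 0.606 with an estimated correlation, and 1 rose and 8 fell when adjusted over the list alone. The ER stress call was lost without nontumor array 1 or 2, without tumor array 1, 2 or 4 and with nontumor arrays 3 and 4 alone (adjusted p from 0.0557 to 0.244). It was also lost with the title number as a block (adjusted p = 0.063). The ER stress median was -0.18, and -0.08 without nontumor array 1.

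Copper handling genes were called lower, while 2 rose and 9 fell of 17. Copper handling had adjusted p = 0.0183, and adjusted p = 0.393 with an estimated correlation, and 2 rose and 9 fell when adjusted over the list alone. The copper call was lost with means per gene and with nontumor arrays 3 and 4 alone (adjusted p from 0.0779 to 0.0799). The importer Slc31a1 fell (-1.40 ± 0.17), and Slc31a2 (1.39 ± 0.12) and the copper-binding prion protein Prnp (3.50 ± 0.29) rose. The metallothionein Mt2A, which binds copper and zinc, was lower (-1.43 ± 0.48, adjusted p = 0.0271), a call lost without nontumor array 3 or 4 or tumor array 2 (adjusted p from 0.0609 to 0.0715). Mt1 did not pass (-0.34 ± 0.24, adjusted p = 0.241). Ceruloplasmin, Cp, the copper carrier of plasma, fell by its brightest probe set (-0.53 ± 0.13, adjusted p = 0.00807), while the mean over its probe sets rose (0.27, adjusted p = 0.0445). The brightest Atp7b probe set was lower by little (-0.25 ± 0.06, adjusted p = 0.00746) and the other was not called lower. Where they lie relative to the LEC deletion is unknown, so they check no label. Of iron handling genes 3 rose and 9 fell of 14, with hemojuvelin, Hjv (-4.05 ± 0.72), the transferrin receptor Tfr2 (-3.61 ± 0.70) and the iron hormone hepcidin, Hamp (-3.40 ± 0.76), among the falls. Their differences were -3.38, -2.92 and -2.59 without tumor array 4, and that of Hjv was -4.71 without tumor array 3. Iron handling had adjusted p = 0.0157, and adjusted p = 0.393 with an estimated correlation, and 3 rose and 10 fell when adjusted over the list alone. The iron call was lost with means per gene and with nontumor arrays 1 and 2 alone (adjusted p from 0.0507 to 0.0519). The iron list median was -1.0, and -0.61 without tumor array 4.

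Among tumor-associated genes the glycoprotein Gpc3 (2.19 ± 0.23) and the glutathione transferase Gstp1 (1.62 ± 0.44, adjusted p = 0.011) rose, and the fetal plasma protein Afp fell (-2.85 ± 0.34). A further Gpc3 probe set was not called higher. Ggt1 (1.13 ± 0.46, adjusted p = 0.0563) and Alb (-0.62 ± 0.34, adjusted p = 0.13) did not pass, and nontumor array 4 stood lowest for Alb (14.53, next 14.57). On the nontumor arrays Alb lay near the highest of all values (14.59), so the size of its difference is uncertain. As lists, liver tumor markers (12 rose and 5 fell of 24, adjusted p = 0.224), glycolysis (11 rose and 3 fell of 16, adjusted p = 0.0678) and interferon response genes (12 rose and 6 fell of 27, adjusted p = 0.709) were not called by camera. Fry called liver tumor markers (adjusted p = 0.00182) and glycolysis (adjusted p = 2.6e-05) higher, but not interferon response genes (adjusted p = 0.151). The p53 targets (2 rose and 5 fell of 20, adjusted p = 0.237), Wnt and perivenous genes (5 rose and 8 fell of 14, adjusted p = 0.404), hypoxia response (8 rose and 4 fell of 17, adjusted p = 0.817) and housekeeping genes (5 rose and 2 fell of 10, adjusted p = 0.44) were not called by camera either. Hypoxia response (adjusted p = 4.9e-04) and housekeeping genes (adjusted p = 0.00102) were called higher by fry, and p53 targets (adjusted p = 0.19) and Wnt and perivenous genes (adjusted p = 0.763) were not. The hypoxia median was 0.32, with 0.07 after quantile normalization again and 0.22 with array medians subtracted. For housekeeping genes these were 0.16, 0.04 and 0.06. Fry was not run on rescaled values, so these 2 calls cannot tell higher expression from a shift of scale. For Wnt and perivenous genes camera gave a lower and fry a higher direction.

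By limma, 19845 of 31042 probe sets (63.9%) differed between tumor and nontumor arrays, 9834 higher and 10011 lower in tumor, and 5037 of them were at least 2-fold apart. With each array's median subtracted, which shifted the median difference of all probe sets by -0.10, 8524 were higher and 13052 lower. The share higher moved from 49.6% to 39.5%, and without dim probe sets it was 64.3% (6879 higher and 3820 lower). Counted over genes, 9658 of 14217 changed, 5511 up and 4147 down. More genes fell than rose after quantile normalization again (4379 up and 4825 down) and with array medians subtracted (4843 and 5188). Of all 14217 genes 9073 (63.8%) did not overlap between the groups, where chance gives 2.86%. Of 35 gene lists, camera called 24, 5 higher and 19 lower. With an estimated correlation camera called 0 (1 at an unadjusted p), and fry called 31. Control RNA added at hybridization differed by at most -0.35 (bioB) between tumor and nontumor arrays. Probe sets for absent bacterial RNA lay at 4.34 ± 0.01 in tumor and 4.56 ± 0.08 in nontumor arrays. The 3' minus 5' signal of beta-actin, a sign of RNA quality, was 0.23 ± 0.09 in tumor and 0.46 ± 0.05 in nontumor arrays, and that of GAPDH 0.59 ± 0.08 and 0.58 ± 0.05.

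LEC nontumor liver at 67 weeks was set against the LEA control of the same age, which is 1 array. Errors here pool the spread of nontumor and tumor arrays, so a gene that did not pass may still differ. Mt2A lay at 13.88 to 14.39 on nontumor arrays and 12.83 on LEA, but at 11.32 to 13.64 on tumor arrays. Hamp lay at 12.84 to 13.38 on nontumor arrays and 13.49 on LEA, but at 7.27 to 11.40 on tumor arrays. The amino acid oxidase Dao was higher in LEC (6.03 ± 0.69, adjusted p = 0.00771), at 10.83 ± 0.36 (n = 4) against 4.80. The LEA levels of Dao and Celf5 lay within the range of probe sets for absent RNA. The RNA-binding proteins Ythdf2 (2.63 ± 0.14) and Celf5 (2.38 ± 0.30), the antibody joining chain Jchain (2.53 ± 0.30), the iron-binding protein Pir (2.19 ± 0.34) and Mab21l3 (2.12 ± 0.26) were higher. So were collagen Col1a1 (2.10 ± 0.35), Tes (1.96 ± 0.30), integrin Itga6 (1.88 ± 0.26) and Nipal2 (1.84 ± 0.27). Further probe sets of Ythdf2, Jchain, Col1a1, Tes and Itga6, and of Slc9a9 among the falls, were not called in the same direction. Cpa1, a carboxypeptidase of the pancreas, was 35.4-fold lower in LEC (-5.15 ± 0.37, adjusted p = 5.0e-04), with 12.22 on the LEA array. The muscle adaptor Stac3 (-5.04 ± 0.17), the desaturase Scd2 (-4.34 ± 0.53), Fam111a (-3.63 ± 0.28), the aldehyde dehydrogenase Aldh1b1 (-3.61 ± 0.49) and the cytokine receptor Lifr (-3.36 ± 0.24) were lower. Cox8b (-2.77 ± 0.26), Slc9a9 (-2.72 ± 0.32), Gcnt2 (-2.43 ± 0.23) and A2ml1 (-2.33 ± 0.38) were lower as well. Among these, nontumor array 1 stood lowest for Celf5 (7.63, next 8.30) and nontumor array 3 stood highest for Fam111a (6.86, next 6.12). Pir, Tes and A2ml1 lost their calls without nontumor array 2 or 3 (adjusted p from 0.0536 to 0.0964) and Nipal2 without nontumor array 3 (adjusted p = 0.0651). Dao, Stac3, Cpa1 and other genes with no second well expressed probe set were not checked for sequence variants under the probes.

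**Figure D4:**
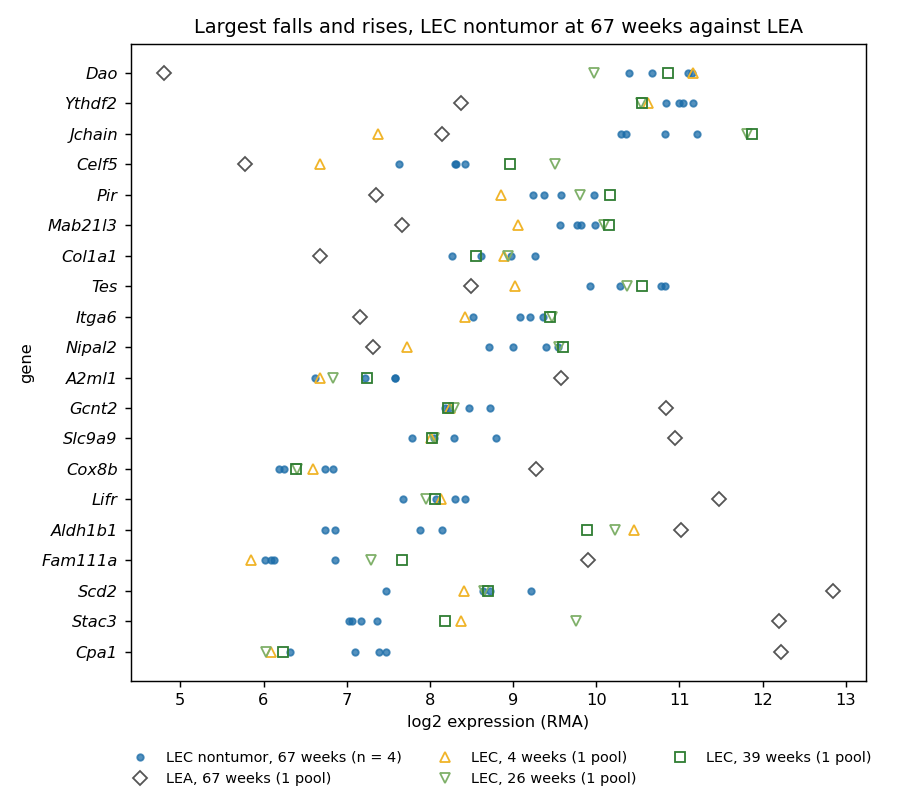
Log2 expression of the 20 genes with the largest rises and falls between LEC nontumor liver at 67 weeks (blue points, 4 arrays) and the LEA pool (diamonds), with the LEC pools at 4, 26 and 39 weeks; each symbol is a single array. Dao lies at 4.80 in LEA and Stac3 at 12.20.

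Atp7b was lower in LEC by its brightest probe set (-0.58 ± 0.10, adjusted p = 0.0469), not by the other, a call lost without nontumor array 1, 2, 3 or 4 (adjusted p from 0.0564 to 0.109). Mt2A (1.32 ± 0.76, adjusted p = 0.535), Mt1 (-0.25 ± 0.38, adjusted p = 0.833), Cp (-0.04 ± 0.21, adjusted p = 0.955) and Hamp (-0.37 ± 1.20, adjusted p = 0.931) did not pass. Nor did Gstp1 (0.68 ± 0.69, adjusted p = 0.741), Afp (-0.10 ± 0.53, adjusted p = 0.958), Ggt1 (1.71 ± 0.73, adjusted p = 0.392), Gpc3 (1.20 ± 0.36, adjusted p = 0.235) and Alb (-0.03 ± 0.53, adjusted p = 0.989). Matrix and stellate cell genes were called higher in LEC than in LEA, with Col1a1 and Col3a1 (1.36 ± 0.21) the 2 of 38 genes past the test. The matrix list had adjusted p = 2.1e-11, and adjusted p = 0.943 with an estimated correlation, and 12 rose and 1 fell when adjusted over the list alone. Col1a1 lost its call without nontumor array 2, 3 or 4 (adjusted p from 0.0544 to 0.112) and Col3a1 without nontumor array 1, 2 or 3 (adjusted p from 0.0519 to 0.0804). NRF2 targets were called higher, with Pir and the exporter Abcc3 (1.57 ± 0.21) the 2 of 24 past the test; tumor array 3 stood lowest for Abcc3 (8.89, next 9.38). NRF2 targets had adjusted p = 5.1e-05, and adjusted p = 0.943 with an estimated correlation, and 3 rose when adjusted over the list alone. Their median was 0.55, and 0.31 with nontumor arrays 1 and 2 alone. Cell cycle genes were called higher, with cyclin Ccnd1 (1.41 ± 0.18) the 1 of 46 past the test. Cell cycle genes had adjusted p = 1.1e-12, and adjusted p = 0.943 with an estimated correlation, and 2 rose when adjusted over the list alone. Their list median was 7.37, 7.25, 8.08 and 8.23 on nontumor arrays 1 to 4 and 7.27 on the LEA array. The median change of the members was 0.56, 0.24 with nontumor arrays 1 and 2 alone and 0.85 with arrays 3 and 4 alone, settings chosen after seeing the data.

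Liver tumor markers were called higher in LEC without a member past the test (median 0.69). Liver tumor markers had adjusted p = 0.0014, and adjusted p = 0.943 with an estimated correlation, and 2 rose and 1 fell when adjusted over the list alone. The median was 0.19 with nontumor arrays 1 and 2 alone and 1.0 with arrays 3 and 4 alone, settings chosen after seeing the data. Bile duct and progenitor genes were called higher in the same way (median 0.60). Bile duct genes had adjusted p = 0.0296, and adjusted p = 0.943 with an estimated correlation, and 3 rose and 1 fell when adjusted over the list alone. The bile duct call was lost without nontumor array 2 or 3, with quantile normalization again, with nontumor arrays 1 and 2 alone and with nontumor arrays 3 and 4 alone (adjusted p from 0.0653 to 0.127). Fatty acid and triglyceride synthesis was called lower without a member past the test (median -0.77). The synthesis list had adjusted p = 0.00322, and adjusted p = 0.943 with an estimated correlation, and no member changed when adjusted over the list alone. The synthesis call was lost with nontumor arrays 1 and 2 alone (adjusted p = 0.0756). Its median was -0.43 with these arrays. Hepatocyte secreted proteins (median -0.05), endothelial genes (-0.09), macrophage genes (0.05), neutrophil genes (0.00) and T, B and NK cell genes (-0.06) were not called. Pancreas, fat and muscle genes were not called as a list (0 rose and 1 fell of 18, adjusted p = 0.51), with Cpa1 as the member past the test. The LEA array was assumed to vary like the replicated groups, and by limma 169 of 31042 probe sets differed, 59 higher and 110 lower in LEC (34.9% higher). Without dim probe sets 55 were higher and 51 lower (51.9% higher). The 3' minus 5' signal of beta-actin was 0.75 on the LEA array and between 0.40 and 0.53 on the nontumor arrays, and that of GAPDH 0.67 and between 0.53 and 0.63. The 4, 26 and 39 week arrays had 0.36, 0.55 and 0.50 for beta-actin. The 169 probe sets included 80 genes, and 128 were at least 2-fold apart. A lone nontumor array against the other 3 gave at most 2 calls, and a lone tumor array at most 78, for array 3. The count was 254 without nontumor array 1, 97 without array 3 and 38 with the spread taken from the nontumor arrays alone. With nontumor arrays 3 and 4 alone, a setting chosen after seeing the data, it was 2831, and with arrays 1 and 2 alone 157. Of 35 lists camera called 6, fry 0 (2 at an unadjusted p), and camera with an estimated correlation 0, also at an unadjusted p.

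Tumor arrays were also set against LEA. The tetraspanin Tspan8 rose 118-fold (6.88 ± 0.55, adjusted p = 5.3e-05), and Krt19 (6.78 ± 0.65), the surface protein Cd24 (6.35 ± 0.47), Dcdc2 (6.35 ± 0.59) and Map2 (6.27 ± 0.43) rose too, with LEA levels of Dcdc2 and Map2 within the range of probe sets for absent RNA. A1bg, a plasma glycoprotein, was lower in tumor (adjusted p = 0.0109), at 13.64 on the LEA array. On tumor arrays 1, 2 and 4 A1bg lay within the range of absent RNA (5.28, 5.31 and 5.10), and tumor array 3 stood highest for A1bg (7.70, next 5.31). Cpa1 (-6.74 ± 0.37), Akr1b7 (-5.93 ± 1.17), Car3 (-5.84 ± 0.97) and Serpina6 (-5.74 ± 1.24) fell, with the tumor level of Cpa1, and Akr1b7 and Serpina6 on tumor array 4, within that range. Akr1b7 and Serpina6 stood at -5.25 and -5.01 without tumor array 4, and Car3 and Serpina6 at -6.46 and -6.36 without tumor array 3. Gpc3 (3.38 ± 0.36, adjusted p = 2.2e-04), Ggt1 (2.84 ± 0.73, adjusted p = 0.0145) and Gstp1 (2.29 ± 0.69, adjusted p = 0.0286) rose, with a further Gpc3 probe set not called higher. Atp7b (-0.84 ± 0.10), Afp (-2.96 ± 0.53) and Hamp (-3.78 ± 1.20, adjusted p = 0.0348) fell. Gstp1 lost its call without tumor array 1 or 2 (adjusted p from 0.0517 to 0.0521) and Hamp without tumor array 2 (adjusted p = 0.0663), and Hamp was -2.96 without tumor array 4. Bile duct and progenitor genes rose in 13 of 15. This bile duct list had adjusted p = 5.8e-07, and adjusted p = 0.446 with an estimated correlation, and 14 rose when adjusted over the list alone. Urea cycle and amino acid breakdown genes fell in 27 of 31. This urea cycle list had adjusted p = 6.2e-09, and adjusted p = 0.446 with an estimated correlation, and 30 fell when adjusted over the list alone. In all, 12280 probe sets differed, 6452 higher and 5828 lower in tumor. With array medians subtracted 5745 were higher and 7959 lower, which moved the share higher from 52.5% to 41.9%, and without dim probe sets it was 62.4%. Of 35 lists camera called 20, or 0 with an estimated correlation (1 at an unadjusted p), and fry 23.

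For the course with age, the 4 nontumor arrays at 67 weeks were set against each younger LEC pool, and differences are 67 weeks minus the younger age. Errors again pool the spread of nontumor and tumor arrays. Against 4 weeks, lipocalin, Lcn2, an iron-sequestering protein of inflammation, was 21.6-fold higher at 67 weeks (4.44 ± 0.44, adjusted p = 0.00853). Cyp3a9 (4.24 ± 0.56), the class I gene RT1-CE5 (3.50 ± 0.44), Jchain (3.29 ± 0.30) and the neutrophil protein S100a9 (3.27 ± 0.39) were higher too. The further Jchain probe set was not called higher. Abcg5, which exports sterols into bile, was 13.2-fold lower at 67 weeks (-3.72 ± 0.34, adjusted p = 0.00573). Its partner Abcg8 (-3.02 ± 0.26), the transporter Slc22a8 (-3.35 ± 0.21), Aldh1b1 (-3.04 ± 0.49) and Zfp354a (-2.99 ± 0.18) were lower. Class II genes were called higher, with RT1-DMa (1.19 ± 0.15) and RT1-DMb (0.93 ± 0.14) the 2 of 8 past the test. Class II genes had adjusted p = 2.9e-09, and adjusted p = 0.632 with an estimated correlation, and 7 rose when adjusted over the list alone. The p53 targets were called higher with no member past the test. The p53 list had adjusted p = 5.3e-04, and adjusted p = 0.632 with an estimated correlation, and 7 rose and 1 fell when adjusted over the list alone. Macrophage genes were called higher, although the member past the test, the endotoxin receptor Cd14, was lower at 67 weeks (-1.24 ± 0.19). Macrophage genes had adjusted p = 9.7e-05, and adjusted p = 0.632 with an estimated correlation, and 7 rose and 1 fell when adjusted over the list alone. Bile acid synthesis and transport was called lower, with Abcg5 and Abcg8 the members past the test. This list had adjusted p = 0.0314, and adjusted p = 0.632 with an estimated correlation, and 1 rose and 3 fell when adjusted over the list alone. Gluconeogenesis and glycogen was called lower, with the regulator Ppargc1a past the test (-1.01 ± 0.16). Gluconeogenesis had adjusted p = 8.2e-04, and adjusted p = 0.632 with an estimated correlation, and 1 fell when adjusted over the list alone. Other lists called higher were cell cycle genes, liver tumor markers, bile duct genes, interferon response genes and NRF2 targets (medians 0.34, 0.53, 0.48, 0.25 and 0.53, adjusted p = 1.9e-04, 0.00451, 0.00451, 0.00422 and 0.0051). These had adjusted p = 0.632 for each with an estimated correlation, and 2 of cell cycle genes, 3 of liver tumor markers, 1 of bile duct genes, 1 of interferon response genes and 3 of NRF2 targets rose and 1 of NRF2 targets fell when adjusted over the list alone. Lcn2 was the tumor marker past the test, and the other 4 lists had no member past it. Lists called lower with no member past the test were fatty acid oxidation genes, fatty acid and triglyceride synthesis genes, cholesterol synthesis genes, respiratory chain genes and Wnt and perivenous genes (medians -0.20, -0.59, -0.46, -0.24 and -0.34, adjusted p = 0.00982, 0.00451, 0.0246, 5.7e-04 and 0.0442). These had adjusted p = 0.632, 0.632, 0.644, 0.632 and 0.632 with an estimated correlation, and 1 of fatty acid oxidation genes and 2 of fatty acid and triglyceride synthesis genes fell when adjusted over the list alone. The cell cycle list median was 7.27 at 4 weeks and 7.37, 7.25, 8.08 and 8.23 on nontumor arrays 1 to 4.

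By limma 117 probe sets differed from 4 weeks, 54 higher and 63 lower at 67 weeks (46.2% higher). The split was 103 higher and 95 lower after quantile normalization again and 48 and 26 without dim probe sets. Of 35 lists camera called 15, fry 0 (4 at an unadjusted p), and camera with an estimated correlation 0 (1 at an unadjusted p). The count of probe sets was 56 without nontumor array 2, 50 without array 3 and 9 with the spread from the nontumor arrays alone. Aldh1b1, Cyp3a9 and RT1-DMb lost their calls without nontumor array 2 or 3 (adjusted p from 0.0551 to 0.0831). Cd14 lost its call without nontumor array 2, 3 or 4 (adjusted p from 0.0506 to 0.0831), Ppargc1a without nontumor array 1, 2, 3 or 4 (adjusted p from 0.0553 to 0.0899) and S100a9 without nontumor array 3 (adjusted p = 0.0518). Afp (0.68 ± 0.53, adjusted p = 0.646) and Mt2A (0.17 ± 0.76, adjusted p = 0.957) did not pass.

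The comparisons with 26 and 39 weeks set arrays with high Xist against the libraries labelled 26 and 39 weeks, which had low Xist and high Eif2s3y. Age and sex cannot be told apart in these comparisons. Against the library labelled 26 weeks, Xist was higher at 67 weeks (11.68 ± 0.23 against 5.27, adjusted p = 7.0e-06). Eif2s3y was lower (3.78 ± 0.04 against 8.90, adjusted p = 9.5e-08). The lower levels of Xist, Eif2s3y and Pbsn lay within the range of probe sets for absent RNA. Probasin, Pbsn (-3.58 ± 0.23), the major urinary protein Mup5 (-3.49 ± 0.46), the retinol dehydrogenase Rdh16 (-3.28 ± 0.33) and the elastase Cela1 (-3.15 ± 0.39) were lower. S100a9 (2.91 ± 0.39), Bdh2 (1.51 ± 0.23), Ntsr1 (0.88 ± 0.11) and Lgals3bp (0.88 ± 0.13) were higher. Further Mup5 probe sets were not called lower. Interferon response genes were called higher at 67 weeks with no member past the test. Interferon response had adjusted p = 7.5e-11, and adjusted p = 0.549 with an estimated correlation, and 12 rose when adjusted over the list alone. Also called higher were macrophage genes, T, B and NK cell genes, neutrophil genes, red blood cell genes and acute phase genes (medians 0.34, 0.14, 0.21, 0.37 and 0.30, adjusted p = 0.00397, 0.00121, 0.00158, 8.3e-05 and 0.0181). These had adjusted p = 0.974, 0.549, 0.349, 0.349 and 0.974 with an estimated correlation, and 2 of neutrophil genes and 3 of red blood cell genes rose when adjusted over the list alone. S100a9 was the neutrophil gene past the test, and the other 4 lists had no member past it. Lower calls were made for fatty acid oxidation genes and matrix and stellate cell genes (medians -0.39 and -0.18, adjusted p = 1.4e-05 and 0.0263). These had adjusted p = 0.549 and 0.974 with an estimated correlation, and 3 of fatty acid oxidation genes and 1 of matrix and stellate cell genes fell when adjusted over the list alone. Sparc, a matrix protein, was the matrix gene past the test (-0.84 ± 0.12), with a further probe set not called lower. Cell cycle genes were called lower, with the replication helicase gene Mcm6 past the test (-0.81 ± 0.11). The cell cycle had adjusted p = 2.7e-08, and adjusted p = 0.733 with an estimated correlation, and 2 fell when adjusted over the list alone. Its list median was 8.31 on the 26 week library and 7.37, 7.25, 8.08 and 8.23 on nontumor arrays 1 to 4. Male-biased genes were called lower, with Mup5 past the test. The male-biased list had adjusted p = 1.0e-06, and adjusted p = 0.549 with an estimated correlation, and 9 fell when adjusted over the list alone. Female-biased genes were called higher with no member past the test. The female-biased list had adjusted p = 8.1e-04, and adjusted p = 0.549 with an estimated correlation, and 4 rose when adjusted over the list alone.

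Mup5 and Ntsr1 lost their 26 week calls without nontumor array 1 (adjusted p from 0.0526 to 0.0569), Cela1 without nontumor array 1 or 2 (adjusted p from 0.0502 to 0.0526) and S100a9 without nontumor array 1, 2 or 3 (adjusted p from 0.0521 to 0.0818). Bdh2, Lgals3bp, Mcm6 and Sparc lost theirs without nontumor array 1, 2, 3 or 4 (adjusted p from 0.0538 to 0.105). By limma 66 probe sets differed, 13 higher and 53 lower at 67 weeks, and 8 and 15 without dim probe sets. The count was 31 without nontumor array 1 and 5 with the spread from the nontumor arrays alone. Of 35 lists camera called 11, fry 0 (5 at an unadjusted p), and camera with an estimated correlation 0 (2 at an unadjusted p).

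Against the library labelled 39 weeks, Xist (11.68 ± 0.23 against 5.67, adjusted p = 1.2e-05) and S100a9 (difference 3.11 ± 0.39) were higher at 67 weeks. Eif2s3y was lower (3.78 ± 0.04 against 8.18, adjusted p = 3.6e-07), and the lower levels of Xist, Eif2s3y and Pbsn lay again within the range of absent RNA. Differences of Pbsn (-4.05 ± 0.23), Mup5 (-3.62 ± 0.46), Rdh16 (-3.39 ± 0.33) and Slc22a8 (-3.01 ± 0.21) were negative, with a further Slc22a8 probe set not called. Interferon response genes were called higher with no member past the test. The interferon list had adjusted p = 9.4e-13, and adjusted p = 0.439 with an estimated correlation, and 12 rose when adjusted over the list alone. Beside it, higher calls were made for macrophage genes, T, B and NK cell genes, neutrophil genes, red blood cell genes, acute phase genes and female-biased genes (medians 0.24, 0.09, 0.06, 0.46, 0.21 and 1.38, adjusted p = 7.2e-04, 0.0128, 0.0291, 0.00287, 0.0338 and 1.7e-04). These had adjusted p = 0.725, 0.725, 0.439, 0.439, 0.994 and 0.481 with an estimated correlation, and 2 of neutrophil genes, 1 of red blood cell genes and 5 of female-biased genes rose when adjusted over the list alone. S100a9 was the neutrophil gene past the test, and the other 5 of these lists had no member past it. Called lower, with no member past the test, were cell cycle genes, fatty acid oxidation genes and class II genes (medians -0.50, -0.34 and -0.60, adjusted p = 1.6e-07, 7.2e-04 and 0.00673). These had adjusted p = 0.725 for each with an estimated correlation, and 3 of cell cycle genes, 1 of fatty acid oxidation genes and 4 of class II genes fell when adjusted over the list alone. The cell cycle list median was 8.29 on the 39 week library and 7.37, 7.25, 8.08 and 8.23 on nontumor arrays 1 to 4. Male-biased genes were called lower with Mup5 past the test. Male-biased genes had adjusted p = 1.2e-07, and adjusted p = 0.439 with an estimated correlation, and 9 fell when adjusted over the list alone. Mup5 lost its call without nontumor array 1 (adjusted p = 0.0585) and S100a9 without nontumor array 1, 2 or 3 (adjusted p from 0.0559 to 0.0685). In all 46 probe sets differed, 8 higher and 38 lower, a share of 17.4% higher. After quantile normalization again the split was 21 higher and 38 lower, or 35.6% higher, and without dim probe sets 7 and 11. The count was 21 without nontumor array 1, 25 without array 2 and 6 with the spread from the nontumor arrays alone. Of 35 lists camera called 11, fry 0 (4 at an unadjusted p), and camera with an estimated correlation 0 (3 at an unadjusted p).

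Between the pools themselves there is 1 array per age and no test. Xist was 11.36 on the 4 week and 5.27 on the 26 week array, and Eif2s3y 3.80 and 8.90. Age and sex therefore cannot be told apart between these 2 arrays. From 4 to 26 weeks, 704 probe sets were at least 2-fold apart, 536 higher and 168 lower at 26 weeks, against 185 to 1043 between pairs of nontumor arrays. The class II list had a median difference of 1.42 from 4 to 26 weeks. The cell cycle list had 0.86, with 18 of 46 genes at least 2-fold higher. Both lay at percentile 100 among 10000 random lists of the same size and expression, as did liver tumor markers (0.59) and p53 targets (0.64), and the bile duct list (0.48) lay at 99.99. Between pairs of nontumor arrays the same medians differed by up to 0.70 for class II, 0.63 for cell cycle, 0.82 for tumor markers, 0.39 for p53 targets and 0.83 for bile duct genes. Fatty acid and triglyceride synthesis (-0.71) and cholesterol synthesis (-0.47) lay at percentile 0, with 9 of the 20 genes of the former at least 2-fold lower. Nontumor pairs differed by up to 0.99 and 1.32 for these. NRF2 targets (0.35) lay at percentile 100 and interferon response (-0.28), gluconeogenesis (-0.28) and endothelial genes (-0.16) at 0. Nontumor pairs differed by up to 0.43, 0.37, 0.29 and 0.33 for these lists. Male-biased genes had a median of 0.53 and female-biased genes -0.68 between the same libraries, which differ in Xist, with nontumor pairs up to 1.42 and 0.88 apart. From 26 to 39 weeks, 49 probe sets were at least 2-fold apart, 24 higher and 25 lower. Class II (0.28) and NRF2 targets (0.14) lay at percentile 100 and cholesterol synthesis (-0.12) at 0.01. Nontumor pairs differed by up to 0.70, 0.43 and 1.32 for these.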

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

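The check for arrays that stand apart was fixed before the data were examined, and the count by array was chosen after the result was seen. The gap of the highest or lowest array to the nearest, divided by the range of its group of 4 arrays, was compared with the critical value of Dixon's test. This was done in 329 groups of named genes, list medians and measures of control probe sets. It was above in 19, where chance gives about 5%, or 16.45 groups. Of these, 10 had tumor array 3 apart, 3 nontumor array 1, 2 each nontumor arrays 3 and 4, and 1 each nontumor array 2 and tumor array 4. No explanation was tested for these values.

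Tumor array 3 was highest for A1bg (7.70, next 5.31, ratio 0.919), Atf3 (9.96, next 9.20, ratio 0.903), Car3 (8.25, next 6.05, ratio 0.830) and Ccl21 (12.50, next 11.76, ratio 0.854). It was also highest for Ccl6 (11.20, next 10.35, ratio 0.872), Elovl2 (8.09, next 5.93, ratio 0.830), the cholesterol synthesis list median (9.88, next 9.32, ratio 0.938) and the neutrophil and mast cell list median (7.99, next 7.47, ratio 0.881). It was lowest for Abcc3 (8.89, next 9.38, ratio 0.927) and Msln (13.18, next 13.78, ratio 0.860).

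Nontumor array 1 was lowest for Celf5 (7.63, next 8.30, ratio 0.838) and highest for Dhcr7 (12.46, next 12.29, ratio 0.846) and Thrsp (13.82, next 12.66, ratio 0.852). Nontumor array 3 was highest for Cyp7b1 (6.76, next 6.21, ratio 0.872) and Fam111a (6.86, next 6.12, ratio 0.880). Nontumor array 4 was lowest for Alb (14.53, next 14.57, ratio 0.895) and the cytochrome P450 list median (11.07, next 11.85, ratio 0.935). Nontumor array 2 was highest for Msln (9.17, next 8.27, ratio 0.882), and tumor array 4 was lowest for Cyp7b1 (6.54, next 7.11, ratio 0.890).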

How the results depend on the processing

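The settings with only nontumor arrays 1 and 2 or only 3 and 4 were chosen after the data were seen. Leaving out each replicate in turn gave 17418 to 19973 probe sets and 8635 to 9620 genes for tumor against nontumor. It gave 97 to 254 probe sets for LEC nontumor against LEA, 10097 to 12309 for tumor against LEA, and 50 to 167, 31 to 52 and 21 to 40 for 67 against 4, 26 and 39 weeks. It called 23 to 24 lists for tumor against nontumor and 5 to 8 for LEC nontumor against LEA. In the order tumor against nontumor, LEC nontumor against LEA, tumor against LEA, then 67 against 4, 26 and 39 weeks, removing dim probe sets gave 10699, 106, 7656, 74, 23 and 18, with fewer probe sets tested. Means over the probe sets of a gene, with genes counted, gave 9598, 79, 6640, 63, 43 and 27. A 2-fold threshold gave 5037 probe sets and 2970 genes for tumor against nontumor and 5039 probe sets for tumor against LEA. Spread from the nontumor arrays alone, from fewer arrays, gave 38 for LEC nontumor against LEA and 9, 5 and 6 for 67 against 4, 26 and 39 weeks. Array weights gave 192 against 4 weeks and 70 against 39 weeks, quantile normalization again gave 198 against 4 weeks, and nontumor arrays 3 and 4 alone gave 2831 for LEC nontumor against LEA, where arrays 1 and 2 alone gave 157. For these the cause was not tested. At 1.5-fold, 2188 and 353 probe sets differed from 4 to 26 and from 26 to 39 weeks. By camera an estimated correlation left 0 lists for tumor against nontumor (1 at an unadjusted p) and 0 for LEC nontumor against LEA (0 at an unadjusted p), where fry also called 0 (2 at an unadjusted p). Of 4192 calls among the 7761 dimmest probe sets in tumor against nontumor 331 were at least 2-fold, against 2140 of 5623 among the 7761 brightest.

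The title number as a replicate block, for tumor against nontumor, called 18957 probe sets, 18524 of them also called without the block, 9312 genes and 23 lists, without ER stress (adjusted p = 0.063). As a random block it called 20270 probe sets and 9843 genes, with a consensus correlation of 0.0632. The numbers do not establish a pairing: deviations of same-numbered arrays correlated at -0.0816 to 0.142 across probe sets, and 5 of 8 arrays correlated best with their own number.

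Single genes changed sign in 22 cases, and the cause was not tested. Cp for LEC nontumor against LEA became 0.0253 with quantile normalization, 0.0153 with array weights, 0.246 with means per gene and 0.0708 with nontumor arrays 1 and 2, and ranged from -0.0879 to 0.032 leaving out each array, positive without nontumor array 4. With means per gene Cp became 0.266 for tumor against nontumor and 0.512 for tumor against LEA. With nontumor arrays 1 and 2, against LEA, Afp became 0.0232, Mt1 0.0184 and Gstp1 -0.115. With quantile normalization Afp against 26 weeks became 0.00053 and Ggt1 against 39 weeks 0.0205. Ggt1 against 39 weeks ranged from -0.426 to 0.276 leaving out each array, at 0.276 without nontumor array 1 and 0.13 without array 2. Against 26 weeks Ggt1 became -0.129 with array weights and ranged from -0.0176 to 0.684, lowest without nontumor array 3. Alb against 4 weeks became 0.00226 with medians subtracted and ranged from -0.0118 to 0.00365, highest without nontumor array 4. Mt2A against 26 weeks ranged from -0.118 to 0.0551, at 0.0551 without nontumor array 1 and 0.00353 without array 2. In tumor against LEA Mt2A ranged from -0.418 to 0.355, at 0.0349 without tumor array 2 and 0.355 without array 4. Of 1647 values of named genes for tumor against nontumor under all alternatives, 1588 kept their direction and side of the threshold, 53 became weaker and 5 stronger. This was 366 of 425 for LEC nontumor against LEA (50 weaker, 1 stronger), 687 of 708 for tumor against LEA (15 weaker, 3 stronger), 234 of 262 against 4 weeks (26 weaker), 192 of 239 against 26 weeks (42 weaker) and 173 of 184 against 39 weeks (8 weaker). For called lists it was 331 of 384 (53 weaker) for tumor against nontumor and 48 of 66 (18 weaker) for LEC nontumor against LEA.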

Other observations

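The tests of sex, of hepatocyte share, of hybridization, of sequence variants, of lone arrays and of a strain difference at 4 weeks were chosen after the result was seen. Values of some gene groups spread over the 4 nontumor arrays. The cell cycle list median was 7.37 and 7.25 on arrays 1 and 2 and 8.08 and 8.23 on arrays 3 and 4. Female-biased genes lay at 11.85 and 11.71 on arrays 1 and 2 and at 10.43 and 10.17 on arrays 3 and 4. Wnt and perivenous genes lay at 10.04 and 10.09 against 9.03 and 8.62. The bioB control added at hybridization lay at 8.70, 8.76, 8.18 and 8.11 on arrays 1 to 4. These are values of single arrays, and no difference between them was tested.

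The count of calls was compared over the 35 splits of the 8 tumor and nontumor arrays into groups of 4. By limma the real split called 19845 probe sets and 9658 genes and the highest other split 0 of either. So 1 of 35 splits gave as many, the smallest share that 35 splits can give. This argues against chance for both counts without excluding it. The other splits mix tumor and nontumor arrays within a group, which raises their spread and lowers their calls. At an unadjusted p the real split gave 21064 probe sets and the highest other 5039. For lists, 5 of 35 splits called as many as the real 24, the highest other calling 27, so chance cannot be excluded for the count of lists.

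All labels give male rats, but Xist and Eif2s3y set the arrays labelled 26 and 39 weeks apart from the other 10. RNA of both sexes mixed in like amounts within those pools is argued against by Xist, which lay below every other array by 5.68 for its brightest probe set and 5.34 for another, beyond the bound of 3 set against mixing. The remaining probe sets, at 2.61 and 2.36, lay between that bound and the bound of 2 set for mixing, and a small share of female RNA stays open. A hybridization difference from the LEA and 4 week arrays, which have high Xist, is argued against by control RNA. Its class means differed by at most 0.166 between the 26 and 39 week arrays and these arrays. Tumor and nontumor arrays were not in this comparison. The bioB control lay at 7.98 and 7.61 on the 26 and 39 week arrays and at 8.11 to 8.76 on the nontumor arrays. The cre control, also added at hybridization, lay at 12.67 and 12.68 against 13.26 to 13.39 on the tumor arrays. Animals of both sexes behind the labels may account for the split by Xist and Eif2s3y. The male-biased list exceeded the female-biased list by at least 3.75 on the 26 and 39 week arrays. Elsewhere it did so by at most 2.53, on the 4 week array, which has high Xist and low Eif2s3y. Among arrays with high Xist this difference ranged from -4.00 on LEA to 2.53, and from -2.10 to 0.26 on nontumor arrays. The list difference alone therefore cannot show the sex of an array. Xist of 11.36 to 13.12 and Eif2s3y of 3.65 to 3.81 argue against the male label for the other 10 arrays. How the labels came to differ from these values is open.

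In tumor arrays, hepatocyte lists were called lower and bile duct and matrix lists higher, none with an estimated correlation (lowest adjusted p = 0.393). A lower share of hepatocytes alone is argued against, because the lowest bile duct change of a tumor array exceeded the highest endothelial change by 2.11. A hybridization or background difference as the whole cause is argued against by control RNA, which differed by at most 0.351. Of 4192 calls among the dimmest probe sets 77.6% were lower in tumor, between the bounds set for and against a lower background, so for these a background difference cannot be told apart from lower expression. What stays open, as a hypothesis, is that the tumor tissue may differ in its cells' expression, in the share of bile duct and matrix cells, or in both.

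Large differences of single genes separated LEC nontumor liver from LEA. The spread of a lone array is argued against, since lone nontumor arrays gave at most 2 calls against 169, although lone tumor array 3 gave 78. The lone arrays were pools of the same 8 pairs, so they do not cover a spread between separately made pools. Fewer probe sets were called against LEA with the spread from the nontumor arrays alone. For the 30 genes with another well expressed probe set, sequence variants under single probe sets are argued against as the main cause, because the other probe set moved 0.612 as far in the median, against 0.635 in tumor against nontumor. Genes without such a probe set were not tested, and sequence variants may account for some of them. A strain difference present at 4 weeks stays open. At 4 weeks 73.4% of the 169 probe sets differed from LEA by at least 0.5 as much, between the bounds set for and against it. The arrays labelled 26 and 39 weeks gave 88.2% and 87.6%. However, 100 simulations of unchanged arrays sharing the LEA array gave 82.5% (75.1% to 88.8%). Because the shared LEA array alone can give such shares, this test cannot decide the question.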
